A study of Mus musculus with 5 samples.

How the data were processed

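RNA of primary pancreatic acinar cells was sequenced in 5 libraries, 2 from p48-Cre control mice and 3 from Arid1afl/fl;p48-Cre knockout mice, all C57BL/6 at 8 weeks of age. Per the labels' protocols, minced pancreas was digested, filtered and left to recover in serum-containing medium before RNA was extracted with TRIzol, and libraries were made with the TruSeq RNA v2 kit, which captures poly(A) RNA and does not mark strand. The labels give no sequencing batch, sex or animal identifier.

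The deposited files hold whole-number read counts per gene symbol, 23284 symbols per library and no normalization, and no row of unassigned reads. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.9.1, Cuffnorm 2.2.1.2, Cuffdiff 2.2.1.5 and the genome build mm9, without saying which step used which. The annotation, the treatment of reads that match several genes and the strand setting are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes therefore cannot be assigned with certainty. Because no genome of the build mm9 was used here, no coordinates are given. Transcript lengths and sequences for the tests of length and shared sequence came from the GENCODE annotation of a later build, matched by gene symbol.

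From the counts, edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model with group as the only term (glmQLFit with robust estimation, glmQLFTest, two-sided), with TMM factors and filterByExpr, which left 8261 genes. Of these, 2902 (35.1%) had no count in either control. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values in the text scale each library's deposited counts to its total without Rn45s and Lars2, and means are given with the SD over the libraries of a group. Where a group had no count, a bound on the fold was computed as the knockout mean CPM over 3 counts in both controls together, equal to 21.5 CPM. Where it had 1 to 3 counts, a fold between shares is given only as the ratio of pooled shares with its exact 95% binomial interval. The bound is less strict than that interval, whose lower limit for Reg3d was 19.2 against a bound of 24. Floors and intervals cover counting error only.

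In total 31 gene lists (acinar enzymes and regulators, duct and gastric genes, aldehyde dehydrogenases, SWI/SNF, senescence, p53, cell cycle, antioxidant, secretory folding, injury, interferon, MAPK, YAP, retinoid, immediate-early, respiratory chain, sterol, mesenchymal and developmental genes, and markers of 10 other cell types) were fixed before the data were examined, as were the main test and the alternatives not named below as added. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Each list's median was also set against 2000 random lists of tested genes matched on abundance in 20 bins, as a fitted log2 fold change and as a log2 CPM ratio with genes without a control count at the floor, a comparison chosen after the data were examined.

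Genes were named by a rule fixed beforehand. It takes Arid1a, the 12 called genes with the largest rise and the 12 with the largest fall that had a mean of at least 5 CPM and no overlap between groups, and from each list up to 4 called members or, where none was called, the 2 most abundant. Aldh1a1, Ptf1a, Krt19, Sox9, Cdkn1a and Cdkn2a were named whatever their values. Not every gene that the rule takes is reported here. Rn45s, Lars2, Cela2a, Sycn, Reg1, Reg2, Reg3a, Reg3g, Nupr1, Prss1, Prss3, Try10, Egr1, Fos, Hspa5, Snord17, Kcnq1ot1, Prss2, Cela1, Cpa1, Ctrl, Clps, Pnlip, Cel, the sex-linked genes and the further genes named in the closing section were chosen after their values were seen.

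Alternatives were RLE and upper quartile factors, no low-count filter, a filter of 1 CPM in 2 libraries, library sizes without the enzyme list, DESeq2 1.42.0, limma-voom, the replicate number as a replicate block, each library left out in turn, and a minimum of 2-fold. Added after the data were examined were TMM without Rn45s and Lars2, totals without both genes and no TMM, knockout libraries thinned to 69760 counts (the mean of the controls, 20 draws), the 301 genes with a mean of at least 100 CPM, and an estimated correlation without Rn45s and Lars2.

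The test was run on simulated counts with the real library sizes, the common dispersion of 0.279 for every gene and 200 changed genes. A further planted list of genes was raised in the knockouts. For knockout against control, 9194 simulated genes were tested. The test called 56% of genes with a log2 change of 4 and 64% of those at -4, but 4% and 0% of those at 2 and -2, and 1 of 8962 unchanged genes, whose median estimate was 0.89. Unchanged genes had the same simulated level in both groups, the mean share over all 5 libraries. The simulated controls thus held no background of their own and no extra spread, so the rate of false calls need not hold for the real libraries. No pair of libraries held identical values. Over the 301 genes the Spearman correlation was 0.48 between the controls, 0.56 to 0.89 between knockouts and 0.11 to 0.37 between a control and a knockout, across genes, which are not independent replicates. These genes were chosen on the mean over all libraries, and some pass it through the controls alone, which can lower the values between groups.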

Results

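Poly(A)-selected RNA was sequenced from primary acinar cells, the enzyme-secreting cells of the exocrine pancreas, taken from C57BL/6 mice at 8 weeks of age. The control group was 2 libraries from p48-Cre mice, which express Cre recombinase from the p48 (Ptf1a) locus in the pancreas. The knockout group was 3 libraries from Arid1afl/fl;p48-Cre mice, in which Cre removes a floxed part of Arid1a, the gene of a SWI/SNF chromatin remodelling subunit. The labels number the libraries within each group and do not say whether each came from a separate animal, so the p-values measure only the spread between these libraries, which may be technical.

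The control libraries held 291677 and 589798 counts, and the knockout libraries 3471701, 4049215 and 3609099. Rn45s, the ribosomal RNA precursor, took 72.6% and 82.2% of the control counts and 8.5%, 10.9% and 6.8% of the knockout counts. Lars2, whose count stood at 0.0583 to 0.0847 of that of Rn45s in each of the 5 libraries, took 4.23% and 5.61% of the control counts and at most 0.93% in a knockout library. Without both genes, 67514 and 72006 counts remained in the controls against 3155357, 3568906 and 3345121 in the knockouts. At that depth 3 counts, taken as the floor of detection, equalled 44.4 and 41.7 CPM in the controls and 0.951, 0.841 and 0.897 CPM in the knockouts. Depth and Rn45s share separated the libraries exactly as genotype did, so a difference between the groups cannot be told apart from a difference in library quality in any comparison that follows. CPM values scale the counts of a library to its total without Rn45s and Lars2.

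**Figure D1:**
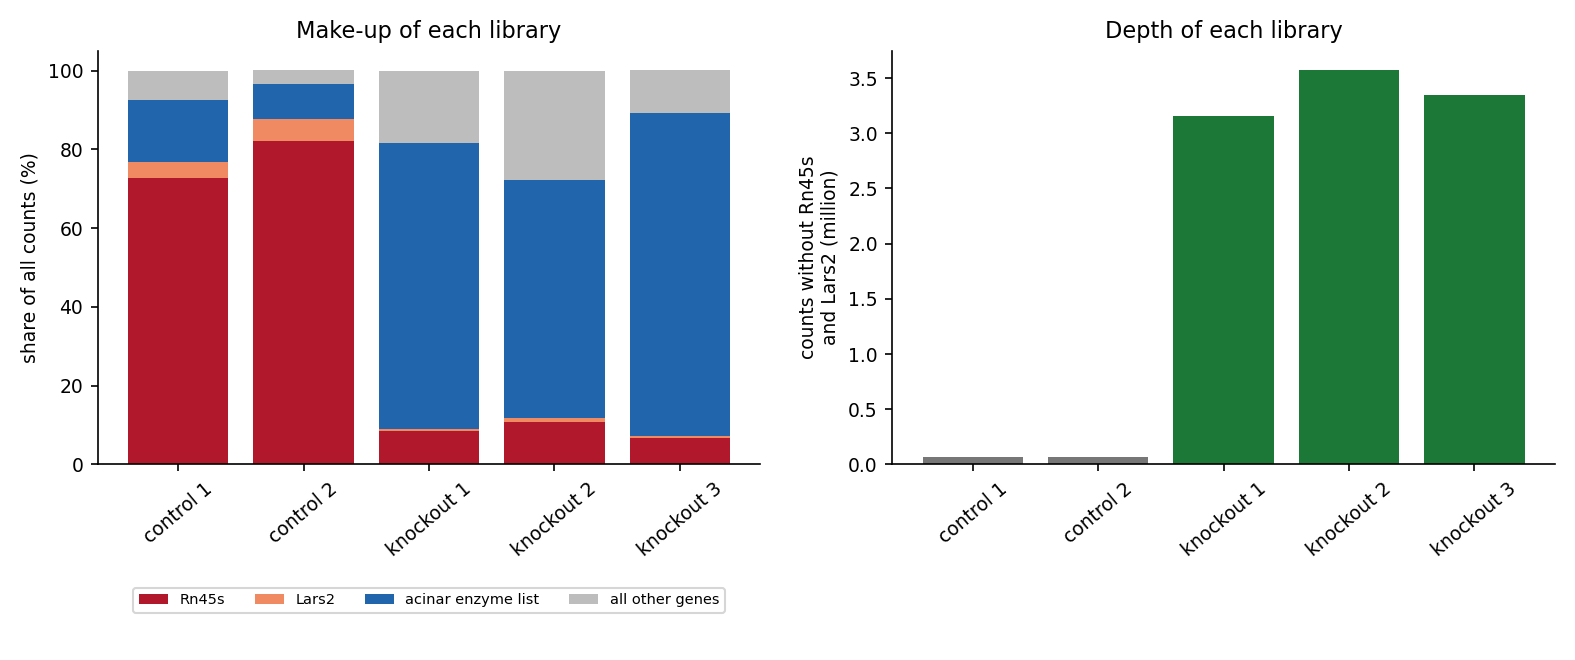
Left, share of each library's counts (%) taken by Rn45s, Lars2, the acinar enzyme list and all other genes, as stacked bars. Right, counts left without Rn45s and Lars2 (bars from 0). The 2 control libraries (grey) hold 67514 and 72006 and the 3 knockout libraries (green) at least 3155357.

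Arid1a, the targeted gene, had 0 and 3 counts in the control libraries and 44, 121 and 42 in the knockout libraries. Pooled within groups this was 21.5 CPM in controls and 20.6 CPM in knockouts, a ratio of 0.956 with an exact 95% interval of 0.323 to 4.67 for counting error alone. The edgeR quasi-likelihood test gave a log2 fold change of 1.64 ± 1.10 (SE; adjusted p = 0.269), and the sign turned with the scaling, to -0.13 with upper quartile factors. A loss of Arid1a RNA was not detectable at this depth. The count of the whole gene also includes exons outside any deleted part, so it does not check the genotype labels.

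The comparison of knockout with control libraries asks which transcripts of acinar cells depend on Arid1a. The Reg family, secreted lectin-like proteins that acinar cells produce in pancreatitis and regeneration, held 2 of the 4 genes that were called higher in the knockout. Reg3b stood at 21.3 ± 9.17 CPM in the controls (SD, n = 2) and 3130 ± 2870 CPM in the knockouts (SD, n = 3). Its pooled ratio was 141, with an exact 95% interval of 48.2 to 684, since the controls held 3 counts in all. The knockout libraries had 6440, 1320 and 1640 CPM of Reg3b, so the size of the ratio depends on knockout 1. Reg3d had no control count and 516 ± 246 CPM in the knockouts, at least 24-fold above the floor of 3 counts over both controls. Gm2663 and 1810009J06Rik, a pair of trypsinogen-like gene models, also had no control count and were at least 25.7-fold and at least 18-fold higher. The exact 95% interval of the pooled ratio had smaller lower limits, 19.2 for Reg3d, 20.6 for Gm2663 and 14.4 for 1810009J06Rik. Reg3d, Gm2663 and 1810009J06Rik have short transcripts of 782, 862 and 882 bases. A median of 2280 bases held for 129 genes with control counts. These were matched in abundance to all 43 genes expected to give at least 10 control counts and with none. The rest of the 43 were less abundant than Reg3d, Gm2663 and 1810009J06Rik, whose expected control counts were 72, 77.2 and 54.1. The median is therefore not one for genes of their abundance. Gm2663 and 1810009J06Rik share 83.5% and 81.5% of their 50-base words with other genes. The counts of these 3 genes are uncertain. The adjusted p-values of these genes from the edgeR quasi-likelihood test were 0.0263 for Reg3b, 0.0428 for Reg3d and Gm2663, and 0.0471 for 1810009J06Rik, and each was higher in 3 of 3 knockout libraries.

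The genes called lower in the knockout numbered 24 of the 8261 tested. Their counts summed over the 3 knockout libraries ran from 0 for Patl2 to 65 for Kcnq1ot1, a long non-coding RNA, and 66 for Snord17. Without control 2, 3 of the 24 were still called, and without knockout 1 there were 5. Mn1, a transcriptional coregulator, had 10 and 16 counts in the controls and 1, 2 and 0 in the knockouts, a pooled ratio of 0.0016 with an exact 95% interval of 0.00031 to 0.00522. Greb1, an oestrogen-responsive gene, stood at 186 ± 11.8 CPM in the controls (SD, n = 2) and 0.293 ± 0.299 CPM in the knockouts (SD, n = 3), with the same pooled ratio and interval as Mn1. Bdnf, a neurotrophin, fell from 126 ± 136 to 0.292 ± 0.281 CPM (pooled ratio 0.00231, interval 0.000436 to 0.00791), and Chek2, a DNA damage checkpoint kinase, from 102 ± 65.5 to 0.28 ± 0.485 CPM (0.00297, interval 0.000547 to 0.0106). AF366264, Pcdhb16, Zfp799, Patl2, Mrgpra9, Nrxn2, Igdcc3 and Trim23 made up the other members of the 12 with the largest fall. None of these 12 genes had more than 3 counts in any knockout library, so each passed the low-count filter through the controls alone. Their calls therefore rest in part on the filter. The adjusted p-values of these 12 genes from the edgeR quasi-likelihood test ran from 0.00534 for Mn1 to 0.019 for Igdcc3. Snord17, a small nucleolar RNA without a poly(A) tail, was called as well, at 603 ± 27.4 CPM in the controls and 6.49 ± 1.69 CPM in the knockouts (adjusted p = 0.0469, edgeR). RNA genes without a poly(A) tail summed to 3730 and 9280 CPM in the controls and 74.8, 124 and 106 CPM in the knockouts. The 1451 olfactory and vomeronasal receptor genes, which serve sensory neurons, summed to 1510 and 1420 CPM in the controls and 11.7, 19.6 and 32.6 CPM in the knockouts.

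The median log2 fold change over all tested genes was 2.05, so a value near 2 marked a typical gene and not a rise. In the main test 2843 of the 8261 genes had an unadjusted p under 0.05 (edgeR). Members called when adjusted over a list alone, as counted below, are to be read against this share. They were not tested against it. Upper quartile scaling lowered that median by 1.59 and called 7 genes higher and 283 lower in place of 4 and 24. TMM scaling without Rn45s and Lars2 called 147 higher, 118 of them with no control count, and 71 lower, and limma-voom called 0 in either direction with 1900 genes at an unadjusted p under 0.05. Without control 1 or without control 2 no gene was called higher, and without knockout 3 the counts were 310 and 163.

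Among the acute-phase and pancreatitis-associated genes, 2 of 13 tested members rose over all genes and 11 when adjusted over the list alone. Besides Reg3b and Reg3d, Reg2 stood at 14.8 and 27.8 CPM in the controls and 2700, 697 and 379 CPM in the knockouts (pooled ratio 56.8, exact 95% interval 19.4 to 275). Reg3a and Reg3g had no control count and were at least 12.1-fold and at least 11-fold higher, which fell to 4.29-fold for Reg3a without knockout 1 and 7.23-fold for Reg3g without knockout 3. Reg2, Reg3a and Reg3g did not pass the test over all genes (adjusted p = 0.0544, 0.0625 and 0.0632, edgeR). Nupr1, a stress-response gene of the exocrine pancreas, stood at 1350 ± 780 CPM in the controls and 5180 ± 2310 CPM in the knockouts without passing the test (adjusted p = 0.0673, edgeR). Reg1, from the enzyme list, had 5010 and 6870 CPM in the controls and 35900, 22500 and 20300 CPM in the knockouts (adjusted p = 0.0635, edgeR). Each of these 7 genes had a positive log2 fold change under every scaling tried. That is no separate support, since the sign could hardly turn. Reg3a, Reg3d and Reg3g had no control count, and the others had log2 fold changes of 3.69 or more in the main test. Scaling moved the median over all genes by -1.88 at most. The list as a whole was called higher by camera (adjusted p = 0.000635), and not with an estimated correlation (adjusted p = 0.564). With the 6 members that had no control count set at the floor, the list's median log2 CPM ratio was 3.24, against -1.15 over all tested genes. Both the fitted median and that ratio lay at percentile 100 of random lists matched on abundance, where the islet markers, which were not called, lay at 100 and 97.9.

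**Figure D2:**
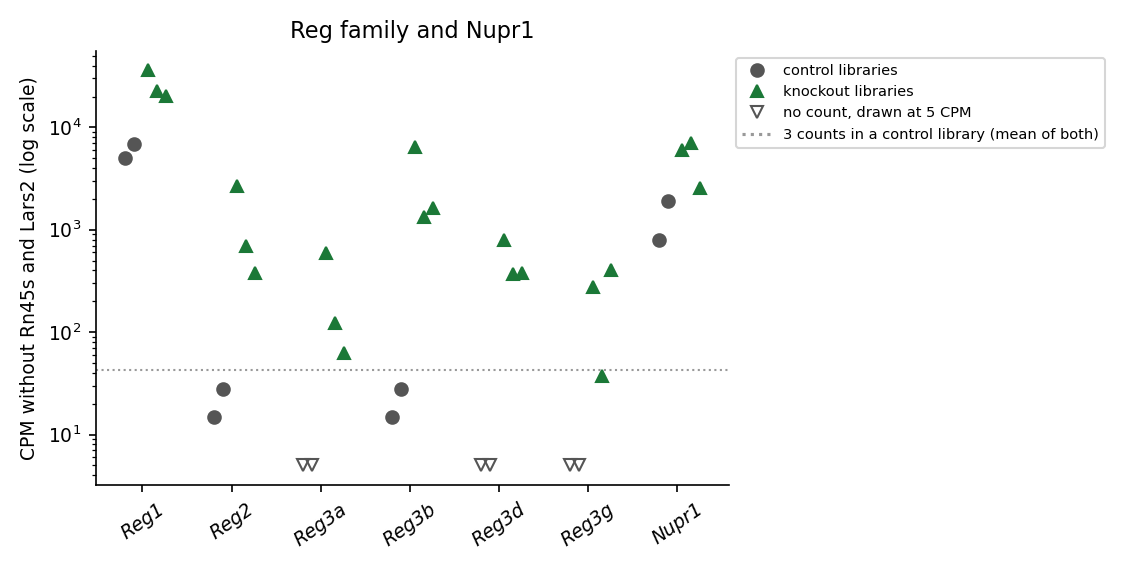
CPM without Rn45s and Lars2 (log axis) of the Reg genes and Nupr1, with a point per library, grey circles for the 2 controls and green triangles for the 3 knockouts. Open triangles mark libraries with no count, drawn at 5 CPM, and the dotted line is the mean of the floors of the control libraries; Reg3b lies at 14.8 and 27.8 CPM in the controls and at 1320 CPM or more in the knockouts.

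Digestive enzymes and granule proteins took 67.5% and 70.9% of the control counts and 79.7%, 68.5% and 88.3% of the knockout counts left without Rn45s and Lars2. Of 36 tested members none passed over all genes and 20 were called higher when adjusted over the list alone. Ctrb1, chymotrypsinogen, stood at 141000 ± 2610 CPM in the controls and 204000 ± 34600 CPM in the knockouts, and Try5, a trypsinogen, at 48700 ± 7250 and 101000 ± 44800 CPM. Cela2a, an elastase, went the other way, with 52300 ± 14800 CPM in the controls and 8920 ± 920 CPM in the knockouts. Its log2 fold change was below 0 in the main test (-0.48, adjusted p = 0.715, edgeR) and in every alternative. It passed with totals without Rn45s and Lars2 (-2.61, adjusted p = 3.99e-05, edgeR), with thinned knockouts and among the 301 genes with a mean of at least 100 CPM, and the adjusted p reached 0.975 without control 2. Sycn, the granule protein syncollin, changed sign with the scaling, from 0.77 to -1.81. Low trypsinogens that share sequence with the abundant ones, Prss1, Prss3 and Try10, had 7.41, 34.7 and 195 CPM in the controls and 219, 901 and 2520 CPM in the knockouts on average (for Prss1 a pooled ratio of 31 with an exact 95% interval of 5.56 to 1230), and their counts are uncertain because reads of near-identical copies can be split between them. Camera called the list higher (adjusted p = 0.00211), and not with an estimated correlation (adjusted p = 0.587), with totals without Rn45s and Lars2, with the replicate block or without knockout 3. Its median log2 fold change of 2.68 lay at percentile 64.7 of random lists matched on abundance, whose median was 2.58, and its median log2 CPM ratio at percentile 35.8.

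**Figure D3:**
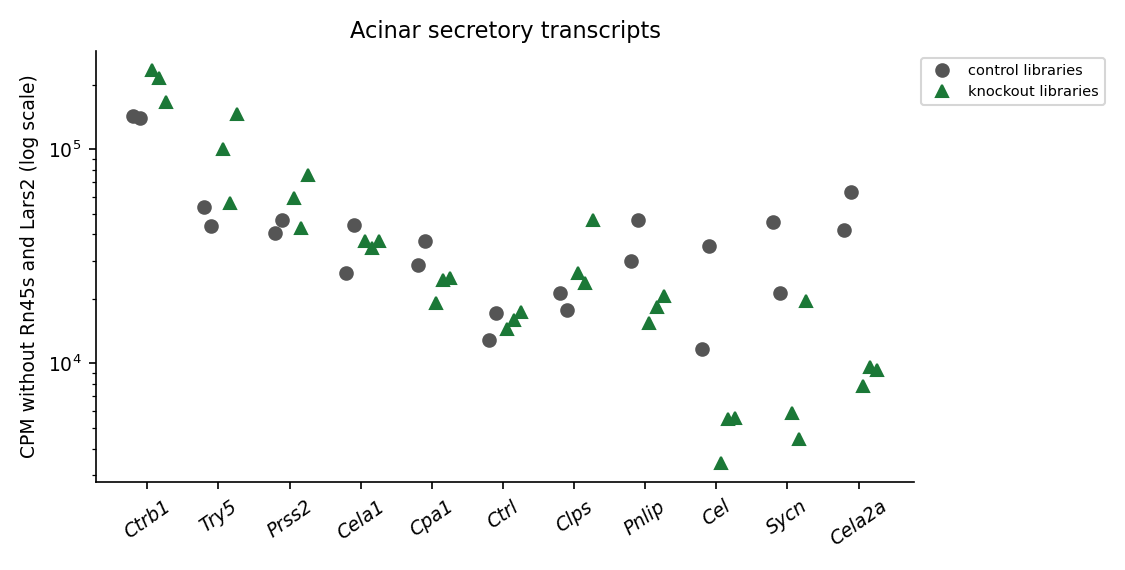
CPM without Rn45s and Lars2 (log axis) of 11 secretory transcripts, with a point per library, grey circles for the 2 controls and green triangles for the 3 knockouts. Ctrb1 is higher in each knockout library than in either control and Cela2a is lower, at 8920 ± 920 CPM against 52300 ± 14800 CPM, and neither changed direction with the scaling.

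Immediate-early genes, which tissue dissociation also induces, were called higher as a list (camera adjusted p = 0.000635; adjusted p = 0.587 with an estimated correlation), with none of 25 members passing over all genes and 14 when adjusted over the list alone. Their sum was 2474 and 1250 CPM in the controls and 5393, 11040 and 777 CPM in the knockouts, so knockout 3 lay below both controls. Egr1 had 0 and 13.9 CPM in the controls and 335, 987 and 26.9 CPM in the knockouts (pooled ratio 64.7, exact 95% interval 11.6 to 2560), whereas Fos had 222 and 278 CPM against 359, 837 and 20.9 CPM. The list's median over all libraries lay at percentile 97.2 of random lists matched on abundance, and at 100 with members without a control count at the floor. Without knockout 2 the list was not called.

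Nuclear-encoded subunits of the respiratory chain (camera adjusted p = 1.72e-05), antioxidant genes (0.0045) and secretory folding genes of the unfolded protein response (0.00487) were also called higher, and with an estimated correlation each had an adjusted p = 0.564. In these lists none of 38, 38 and 34 tested members passed over all genes, against 21, 17 and 6 higher when adjusted over the list alone. Respiratory chain members summed to 2237 and 1486 CPM in the controls and 2494, 3314 and 2151 CPM in the knockouts. Atp5d, of the ATP synthase, had 363 ± 95 CPM in the controls and 199 ± 10.9 CPM in the knockouts, and its log2 fold change of 1.21 turned negative under upper quartile scaling. Fth1, the ferritin heavy chain, had 320 ± 197 and 640 ± 366 CPM. The chaperone Hspa5 had 65.7 ± 53.7 and 423 ± 269 CPM, and the pancreatic disulfide isomerase Pdia2 had 2870 ± 192 and 1560 ± 778 CPM. The folding list turned to lower among genes with a mean of at least 100 CPM, and its median log2 fold change of 2.11 lay at percentile 24 of random lists matched on abundance, whose median was 2.43. The medians of the respiratory chain and antioxidant lists lay at percentiles 96.4 and 94.9. With members without a control count at the floor, the percentiles were 54.5 for folding, 73.2 for the respiratory chain and 98.2 for antioxidant genes. The call of the folding list was lost with upper quartile scaling, with totals, with the replicate block and without knockout 2 or knockout 3, and that of the antioxidant list without knockout 1 or knockout 2.

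Genes of proliferating cells (camera adjusted p = 0.00405), YAP and TEAD targets (0.0074) and sterol synthesis genes (0.0439) were called lower as lists, each with an adjusted p = 0.564 with an estimated correlation. Of 10, 16 and 15 tested members none passed over all genes, and 1 cell cycle gene was lower when adjusted over the list alone. Without control 1 none of these 3 lists was called. With a knockout left out, the cell cycle list had too few tested members for a test. The sterol list was also not called without control 2 or knockout 2, with either other filter or with totals without Rn45s and Lars2, and the YAP list not without a low-count filter. Their medians lay at percentiles 3.8, 0.5 and 1.6 of random lists matched on abundance, for the cell cycle, YAP and sterol lists, and at 7.8, 2.8 and 34.5 with members without a control count at the floor. The control libraries held few counts of these lists, 55 and 31 for the cell cycle, 69 and 55 for YAP targets and 38 and 35 for sterol synthesis. Cdc45, a replication factor, had 1 and 13 control counts and stood at 97.7 ± 117 CPM in the controls and 0.877 ± 0.843 CPM in the knockouts. Srebf2, a transcription factor of sterol synthesis, had 119 ± 106 and 9.3 ± 10.3 CPM, and Cyr61, a YAP target, 131 ± 66.8 and 165 ± 157 CPM. Olfactory and vomeronasal receptor genes were also higher in both controls, as given above.

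Markers of duct cells and metaplasia were not called (camera adjusted p = 0.118), with none of 27 members passing and 8 higher when adjusted over the list alone. The list was called higher without a low-count filter and without control 1, and in the latter its median lay below that of all genes. Krt19 had 51.4 ± 53 CPM in the controls and 213 ± 245 CPM in the knockouts, Krt18 452 ± 345 and 1440 ± 1060 CPM, and Clu 1520 ± 910 and 6170 ± 1920 CPM. Sox9, the ductal transcription factor, had no control count and 23.8 ± 17.3 CPM in the knockouts, with 5.68 CPM in knockout 3, so a difference was not detectable at this depth. Transcription factors and receptors of the acinar programme were not called either (0.389), with 6 higher and 2 lower of 15 when adjusted over the list alone. Ptf1a had no control count and 19.2 ± 13 CPM in the knockouts, below the floor of the control group, and Xbp1 had 98.6 ± 76.6 and 201 ± 110 CPM. Gastric-type mucosal genes (0.0568), called higher with RLE factors, with upper quartile factors and without control 2, had 5 of 8 members higher when adjusted over the list alone, and Gkn3, with no control count, was at least 10.2-fold above the floor, or 5.7-fold without knockout 2. None of the 8 passed over all genes, Gkn3 with an adjusted p = 0.0605 (edgeR). The medians of the duct, acinar regulator and gastric lists lay at percentiles 92.3, 95.9 and 98.8 of random lists matched on abundance, and at 66.4, 62.9 and 73.7 with members without a control count at the floor.

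Aldehyde dehydrogenases were not called (camera adjusted p = 0.314). Aldh1a1 had no control count and 17, 99 and 52 counts in the knockouts, at 16.2 ± 11.2 CPM, which lies below the control floor of 21.5 CPM, so a difference was not detectable at this depth. Aldh2 had 13.9 ± 19.6 CPM in the controls and 33.3 ± 30.5 CPM in the knockouts, a pooled ratio of 2.38 with an exact 95% interval of 0.655 to 19.8. The other SWI/SNF subunits were not called (0.362), with Arid2 at 29.6 and 361 CPM in the controls and 12.8 ± 7.03 CPM in the knockouts. The log2 fold change of Arid2 was -2.11, and 0.698 without control 2. Senescence genes (0.736) and p53 targets (0.808) were not called, and camera placed both toward higher while their median log2 fold changes relative to all genes were -0.11 and -0.67. With members that had no control count at the floor, their median log2 CPM ratios were -0.38 and -0.77, above the -1.15 of all tested genes. Random lists matched on abundance had medians of -0.97 and -1.12. The fitted medians of the senescence and p53 lists lay at percentiles 44.3 and 17 of such lists, and the ratios at 96.6 and 88.8. For the aldehyde dehydrogenase and SWI/SNF lists these percentiles were 88.8 and 5.4 as fitted, and 65.9 and 12.8 at the floor. The p53 targets were called higher only by fry, which does not compare a list with other genes (adjusted p = 0.0135), with Btg2 at 106 ± 66.1 CPM in the controls and 321 ± 235 CPM in the knockouts. Cdkn1a, the p21 cell cycle inhibitor, had 0 and 2 control counts and 122, 243 and 41 CPM in the knockouts. Its pooled ratio was 9.63 with an exact 95% interval of 2.66 to 79.6, and its size depends on knockout 2. Cdkn1a did not pass the test (adjusted p = 0.0632, edgeR). Cdkn2a had 1 control count and 2 knockout counts and was not tested.

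Interferon-stimulated genes (camera adjusted p = 0.12), MAPK targets (0.389), retinoid genes (0.362) and mesenchymal transition genes (0.0952) were not called. The mesenchymal list was called lower with upper quartile factors, with the replicate block and without knockout 3. Of 12 retinoid members, 6 were higher and 1 lower when adjusted over the list alone. The retinoid list lay at percentile 97.4 of random lists matched on abundance, and at 44.1 with its 7 members without a control count at the floor. The mesenchymal, interferon and MAPK lists lay at percentiles 0.5, 2.9 and 38.1, and at 4.1, 23.1 and 65.2 with such members at the floor. Rara, a retinoic acid receptor, had 124 ± 76.6 CPM in the controls and 13.4 ± 9.88 CPM in the knockouts. Ccnd1, cyclin D1, had 171 ± 32.7 CPM in the controls and 27.4 ± 18.4 CPM in the knockouts, Vim 168 ± 119 and 53.9 ± 44.1 CPM, and Ifitm3 14.3 ± 0.653 and 50.5 ± 14 CPM (pooled ratio 3.53, exact 95% interval 0.971 to 29.2), and none of these passed the test. The HOX and developmental list had 3 tested members, too few for a test as a list, and was called lower without a low-count filter (29 tested members) and with 1 CPM in 2 libraries (6 tested members). Its member Hoxa5 stood at 42.6 ± 18.3 CPM in the controls and 1.85 ± 0.927 CPM in the knockouts.

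Markers of other cell types in the pancreas were not called for macrophages (camera adjusted p = 0.121), lymphocytes (0.267), fibroblasts (0.0536), endothelium (0.179), islet cells (0.167) or adipocytes (0.354). Fibroblast markers were called lower with the replicate block, and endothelial markers higher without a low-count filter. When adjusted over the list alone, 5 of 10 macrophage, 8 of 15 endothelial, 5 of 14 islet and 1 of 8 adipocyte markers were higher. On the same basis 1 endothelial and 1 adipocyte marker were lower. The percentiles among random lists matched on abundance were 95.7, 99.5, 99.9 and 100 for macrophages, lymphocytes, endothelium and islet cells, and 96.1, 20.5, 54 and 97.9 with members without a control count at the floor. Fibroblasts and adipocytes lay at percentiles 4.2 and 14.1, and at 28.6 and 2.4 with such members at the floor. Macrophage markers summed to 222.2 and 277.8 CPM in the controls and 240.9, 818.7 and 174.6 CPM in the knockouts, and islet markers to 118.5 and 736 CPM against 247.2, 1273 and 302.2 CPM, with Ins2 at 294 ± 311 and 177 ± 151 CPM. Adipocyte markers summed to 592.5 and 722.2 CPM in the controls and 230.1, 223 and 96.86 CPM in the knockouts, and Lpl had 371 ± 250 and 78.6 ± 7.57 CPM. Lymphocyte markers summed to 444.4 and 125 CPM against 45.32, 229.5 and 50.52 CPM, and camera placed the list toward lower while its fitted median lay above that of all genes because 7 of 12 members had no control count, and with these at the floor the median log2 CPM ratio was -1.83. Fibroblast markers summed to 429.5 and 458.3 CPM against 111.9, 414.1 and 50.82 CPM, and endothelial markers to 177.7 and 236.1 CPM against 303.3, 378 and 96.86 CPM. Neutrophil, mesothelial and neural markers had 2 tested members each and red cell markers none, too few for a test, and haemoglobin and other red cell genes had no control count and at most 3 counts in a knockout library.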

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

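The number of called genes changed with the scaling, the filter, the tool, the block and the libraries used, and held at 4 higher and 24 or 25 lower with a minimum of 2-fold or library sizes without the enzyme list. None of the 28 called genes changed direction in any alternative that tested it. Reg3d, Gm2663 and 1810009J06Rik had no control count and Patl2 no knockout count, so their sign could not turn. Scaling moved the median by -1.88 at most, so it tested the direction of large changes only weakly. The unchanged direction is therefore no evidence of stability. The 4 genes called higher were also called in all alternatives except limma-voom and the fits without control 1 or control 2. Genes called higher, 4 in the main test, were 7 with upper quartile factors, 1076 without a low-count filter, 336 with 1 CPM in 2 libraries, 656 with DESeq2 and 0 with limma-voom. Genes called lower, 24 in the main test, were 283, 710, 131, 551 and 0 in the same order, and 51 with RLE factors. Of these 24 genes, 24 stayed called with RLE and upper quartile factors, with either filter and with DESeq2, but 14 without control 1, 3 without control 2, 5 without knockout 1, 19 without knockout 2, 21 without knockout 3, 3 among genes with a mean of at least 100 CPM and 7 in each draw of thinned knockouts. Not all 24 were tested in every fit. Among the alternatives added after the data were examined, TMM without Rn45s and Lars2 gave 147 higher and 71 lower, totals without both genes gave 16 and 134, genes with a mean of at least 100 CPM gave 16 higher, and thinned knockouts gave a median of 19 higher (13 to 26 over 20 draws). The fits to abundant genes and to thinned knockouts tested 301 and 280 to 299 genes in place of 8261, and the cause of the other changes was not tested. Scaling moved the median log2 fold change of 2.05 by -0.43 with RLE factors, -1.59 with upper quartile factors, -0.12 with TMM without Rn45s and Lars2 and -1.88 with totals.

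Leaving out each library gave 0 to 310 genes higher and 5 to 163 lower. Without control 1 there were 0 and 111, without control 2 there were 0 and 12, without knockout 1 there were 6 and 5, without knockout 2 there were 89 and 46, and without knockout 3 there were 310 and 163. With a control left out, the other was assumed to vary like the knockouts.

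The replicate numbers of the groups are shared, but differences between numbers 1 and 2 did not go together across groups (correlation -0.06 over 301 genes). The controls hold few counts per gene and had a Spearman correlation of 0.48 with each other. Noise in the controls could hide a shared preparation, so a pairing is not excluded. With the number as a replicate block, 23 genes were higher and 2 lower, the 4 genes called higher among the former and none of the 24 among the latter, and 4 lists were higher and 5 lower, the latter with the mesenchymal and fibroblast lists.

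Lists called higher, 6 in the main test, were 0 with an estimated correlation, with or without Rn45s and Lars2, 1 with fry (p53 targets), and 1 (acute-phase and pancreatitis-associated genes) both among genes with a mean of at least 100 CPM and in thinned knockouts. Lists called lower, 3 in the main test, were 0 in each of these, though the last pair of fits could not test them. Duct, gastric, mesenchymal, fibroblast, endothelial and HOX lists, not called in the main test, were each called in 1 to 3 alternatives. Leaving out each library gave 3 to 7 lists higher and 0 to 3 lower, with 3 and 1 without knockout 2 and 0 lower without control 1. Arid1a changed sign, to -0.13 with upper quartile factors and -0.128 with totals, and rose to 8.81 without control 2, which holds its 3 control counts. Arid2, not called in the main test, changed from -2.11 to 0.698 without control 2. Sycn, not called in the main test either, was called lower at -1.81 with totals. Secretory folding genes turned from higher to lower, with a median of -0.096 relative to all genes, among genes with a mean of at least 100 CPM. The cause of these reversals was not tested. The pseudocount alternatives did not apply, since the files hold counts.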

Other observations

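The tests of receptor genes, of RNA without a poly(A) tail, of sampling and of Arid1a loss were chosen after the result was seen, as were the fit to abundant genes and the genes named in this part, apart from Arid1a, AF366264, Patl2, Reg3d, Gm2663 and 1810009J06Rik. Among the 301 genes with a mean of at least 100 CPM, edgeR called 16 higher and 18 lower in the knockouts, against 4 and 24 over all tested genes. Besides Reg genes and trypsinogens, those higher included Ang, an angiogenin ribonuclease (pooled ratio 42.1, exact 95% interval 7.56 to 1670, adjusted p = 0.0275), and Glycam1 (18.9, 6.45 to 91.5, adjusted p = 0.0296), and Amy1, an amylase (103, 18.5 to 4080), which had 1300, 896 and 46 CPM in the knockouts. Rps21, a ribosomal protein gene, had no control count and 283, 244 and 253 CPM in the knockouts, at least 12.1-fold above the floor. S100g, a calcium-binding protein gene, was at least 9.43-fold and Lrg1, an acute-phase gene, at least 9.45-fold above it, or 5.69-fold without knockout 1 for Lrg1. Those lower were led by AF366264 (adjusted p = 0.00271, edgeR), by Kcnq1ot1, Mir5109 and Snord17 (0.00347 each), and by Rmrp and Rpph1 (0.0091 each). Snord17, Rmrp and Rpph1 are RNAs without a poly(A) tail. Also lower were Malat1, a nuclear long non-coding RNA, at 1880 ± 147 CPM in the controls (SD, n = 2) and 192 ± 192 CPM in the knockouts (SD, n = 3), and Ldha, lactate dehydrogenase (-2.85 on the log2 scale, adjusted p = 0.0442). Malat1 was not called in the main test (adjusted p = 0.147, edgeR). The mean of at least 100 CPM runs over all 5 libraries, so a gene can pass it through the controls alone. Atp8b3, called lower, had 0 and 42 control counts and 0, 2 and 0 knockout counts. The lower calls among the 301 genes therefore rest in part on the filter.

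A first pattern is the set of 24 genes called lower in the knockout, whose knockout counts summed to between 0 (Patl2) and 66 (Snord17). The 12 with the largest fall passed the low-count filter through the controls alone. Background reads from genomic DNA or unspliced RNA in the control libraries were tested on the receptor genes. The lowest control share of these genes was 43.5 times the highest knockout share. Of them, 4 reached 12 counts over both controls, the smallest sum among the called genes. The 102 receptor counts of control 1 fell on 25 genes and the 102 of control 2 on 13. The knockouts spread 37, 70 and 109 counts over 32, 64 and 58 genes. Control counts thus sat in few receptor genes, so the summed share alone does not show background spread over the genome. Background in proportion to exonic length predicted a rank correlation between control count and transcript length among genes under 1 CPM in the knockouts, and it was 0.19 over 11911 genes (permutation p = 0.000999, the smallest that 1000 permutations can give). Counts of true transcripts also rise with length, and the called genes were not tested as a set. The correlation therefore cannot tell background from low expression. Carry-over of RNA without a poly(A) tail had the values it needs for Snord17 alone, with Rmrp, Rpph1, small nucleolar and similar RNAs at 30.1 times the share, and says nothing about the 23 called genes outside these classes. An effect of Arid1a loss on these genes cannot be told apart from library quality, since the lowest control share of Rn45s was 6.66 times the highest knockout share.

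A second pattern is that 43 of 435 genes expected from the knockouts to give at least 10 control counts had none, Reg3d, Gm2663 and 1810009J06Rik among them. For sampling at the control depth as the whole cause, a negative binomial with the common dispersion gives 0.171 such genes. Knockouts 1, 2 and 3 thinned to the same depth had no count for 0 of 445, 1 of 333 and 36 of 559 genes. Knockout 3 thus came near the controls, so sampling together with the spread between libraries is not excluded. Loss of short transcripts may account for part, since the 43 genes had a median transcript length 0.62 times that of 129 genes of like abundance (1408 against 2280 bases, permutation p = 0.0009). Reads shared with near-identical genes remained open, with 6.5 percentage points more shared 50-base words in the 43 genes (95% bootstrap interval -0.3 to 14.2, permutation p = 0.0634); the share was 83.5% for Gm2663 and 81.5% for 1810009J06Rik and 0% for Reg3d. An effect of Arid1a loss cannot be told apart from depth, since the lowest knockout total was 43.8 times the highest control total.

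Xist had 0 and 0 counts in the controls and 272, 1 and 204 in knockouts 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y and Uty had no count in any of the 5 libraries, and Kdm5d had 1, in knockout 3.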
